A study of Ophiomastix wendtii with 16 samples.

How the data were processed

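RNA was measured by sequencing of poly(A)-selected, strand-marked libraries from the brittle star Ophiomastix wendtii. Per the labels, 16 libraries came from 3 adult animals: 6 of the inner arm core, 4 of whole arm segments and 6 of the stomach. Each animal gave 2 core and 2 stomach libraries, and whole arm libraries numbered 2 for animal 1 and 1 each for animals 2 and 3. Groups were taken from the tissue label. In 1 library the title speaks of the inner arm core while the tissue label, the source name and the sample code say stomach, and it was counted as stomach.

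The data analysed here are a single table of differential expression that the authors deposited, with 1 row for each of 322502 assembly genes and no column for any library. Gene identifiers have the form that the Trinity assembler writes (component, cluster and gene number). The submitters' processing notes list FastQC 0.11.9, RSEM 1.3.3, Bowtie2 2.5.1 and edgeR 3.18, the last without saying whether this is the number of the package or of a software release that holds it. RSEM estimates counts and divides reads that fit several assembly genes among them, so near-identical assembly genes can share reads, and values of such genes are uncertain. The assembler settings, the filter on low counts, the normalization, the model and the use of the animal in it are not given in the sources used here.

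Per the file headers, each row holds an up or down tag, a fold change, a log2 fold change, a mean abundance in log2 CPM (counts scaled to a common library total), a likelihood ratio statistic, a p-value and an adjusted p-value (false discovery rate). The fold column that the authors deposited is a signed score, which equalled the signed power of 2 of the log2 fold change in all 322502 rows within a relative tolerance of 1e-06. The p-value the authors deposited equalled the chi-square tail of the likelihood ratio score with 1 degree of freedom in all rows at the same tolerance on the log scale. The deposited adjusted p-value equalled the Benjamini-Hochberg adjustment over all 322502 genes. The tag matched an adjusted p under 0.05 together with a fold of at least 2 in every row. A gene is called here when it carries the authors' tag.

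The header of the table gives neither the tissues compared nor which of them a positive fold change favours, and no tissue was inferred from the values. Directions are therefore given as positive and negative. The library values behind the table were not analysed here, so depth per library, the spread between animals and standard errors are unknown. No value carries an SD or n, no floor or counting interval is given for a gene, and p-values are the authors' own.

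Before the data were examined, tests of core against whole arm, core against stomach and whole arm against stomach had been planned on counts per library, summed by animal and with the animal as a block, together with tests of genes above both other tissues, of graded genes, of differences between animals and of 13 gene lists. The lists were fibrillar collagens, matrix glycoproteins, matrix proteases, neurons and secretory granules, neural transcription factors, muscle, digestive gland, biomineralizing cells, ciliated epithelium, germline, coelomocytes, ribosomal proteins and oxidative phosphorylation. None of these tests could be run on a table of fold changes, and no list gave a result, because the table does not pair its identifiers with gene names. Their place is taken by descriptions of the authors' comparison.

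The rule for named genes, also fixed beforehand, took the 2 largest folds in each direction among called genes with a mean of at least 10 CPM. Its further condition, the same direction in all 3 animals, could not be applied. The gene with the highest mean abundance was added after its values were seen.

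Counts of called genes were tallied by direction, fold size and mean abundance with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Mean CPM is 2 to the power of the deposited log2 value, which holds a prior amount, since these values sum to 1137634 over all genes. Shares of calls carry exact (Clopper-Pearson) 95% binomial intervals, which treat genes as independent, although genes are not independent replicates. The share of unchanged genes was estimated from the density of p-values above 0.5. Identifiers without the gene number were used as assembly clusters, and pairs of called genes in a cluster were compared with 1000 random reassignments of direction among called genes of the same abundance class. An outer band of fold against abundance was delimited, among genes of at least 1 CPM and 16-fold difference, by the widest empty interval of the log2 fold less the log2 of CPM above the table's lowest CPM. The interval was then looked up in genes of 0.5 to 1 CPM, which had no part in placing it.

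For the test of library scaling, log2 fold changes were moved by their median and p-values recomputed from the error that each likelihood ratio implies. On 20000 simulated genes with 200 changed by 3 on the log2 scale, this step recovered 90.0% of the changed genes, against 90.5% computed from the errors put in, and found a shift of 0.24 where 0.25 had been put in. The simulated statistics had normal errors and the same form that the step inverts, so this checks the arithmetic only. Whether the implied error holds for genes with few reads was not tested. The closing section gives the effect of other thresholds, adjustments, abundance filters, counting units and scaling.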

Results

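Brittle stars can stiffen and soften their collagenous tissue under nervous control, and the secretory juxtaligamental cells that lie in this tissue are the cells thought to drive the change. The study sampled 3 tissues that differ in these cells: the inner arm core, where they are concentrated, whole arm segments, which hold them at their ordinary level, and the stomach, which lacks them. The 16 libraries comprised 6 of the inner arm core, 4 of the whole arm and 6 of the stomach, taken from the same 3 animals. The processed data analysed here were the authors' deposited table of 1 comparison, which gives a log2 fold change, a mean abundance and a p-value for each of 322502 assembly genes. The table's header does not state which of the tissues were compared, so a positive fold change cannot be assigned to a tissue. Its genes carry assembly identifiers without names or genome positions. The depth of the libraries is unknown.

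The table reports genes that differed in transcript abundance in a contrast whose sides it does not describe, be it a pair of tissues or a tissue against the others. In the authors' deposited table, a total of 41573 genes, 12.9% of those listed, were called at an adjusted p under 0.05 with a fold of at least 2. Of these, 26660 had a positive and 14913 a negative fold change, so that 64.1% of the calls were positive (95% interval 63.7 to 64.6%). Positive calls had a median fold of 15.7, with quartiles of 7.90 and 35.0, and negative calls a median fold of 12.1, with quartiles of 6.01 and 23.2. These folds include those of genes on the outer edge of fold against abundance, described further on, which may not be exact sizes. Without the fold minimum only 25 further genes passed, the smallest of them at 1.90-fold. The density of p-values above 0.5 gave an estimate that 63.2% of the listed genes did not differ. This estimate takes the p-values of unchanged genes to be evenly spread, which was not tested for genes with few reads. An unadjusted p under 0.05 was reached by 85867 genes. How repeat libraries of an animal entered the model is not stated. If they counted as replicates, the p-values, and with them the calls, would overstate the evidence.

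Large folds were frequent. Of the called genes in the authors' deposited table, 26601 differed at least 10-fold, 3396 at least 100-fold, 439 at least 1000-fold and 46 at least 10000-fold. The positive share was 67.4% at 10-fold, 73.2% at 100-fold, 75.2% at 1000-fold and 69.6% at 10000-fold. Of the 439 genes, 307 lay in the outer band of fold against abundance described further on. At like abundance this band lay 0.722 higher on the log2 scale on the positive side, so shares above a common fold may lean positive.

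The largest positive fold among called genes of at least 10 CPM belonged to TRINITY_DN613_c0_g1. The authors' deposited table gives it a log2 fold change of 17.17, a mean of 2376 CPM and an adjusted p of 2.83e-44. TRINITY_DN435_c0_g1 followed, with a log2 fold change of 16.45, a mean of 787.1 CPM and an adjusted p of 2.24e-38 in the authors' deposited table. On the negative side, the authors' deposited table lists TRINITY_DN372_c0_g2 with a log2 fold change of -17.59, a mean of 2894 CPM and an adjusted p of 2.95e-66. It lists TRINITY_DN24708_c1_g1 with -16.96 on the same scale, a mean of 1862 CPM and an adjusted p of 9.49e-45. The gene with the highest mean of all, TRINITY_DN966_c0_g1, stood at 31030 CPM and was not called, with a log2 fold change of 0.12 and an adjusted p of 0.88 in the authors' deposited table. This last gene was chosen after its values were seen. TRINITY_DN435_c0_g1, TRINITY_DN372_c0_g2 and TRINITY_DN24708_c1_g1 lay on the outer edge of the plot of fold against abundance, described further on, where the listed fold rises in step with abundance, so their folds and their order are not exact sizes. TRINITY_DN613_c0_g1 lay outside that edge. A fold of 147158 at a mean of 2376 CPM still places its low side under the lowest listed mean, 0.383 CPM. Its fold and rank are therefore not exact either.

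Most listed genes were of low abundance, and the direction of the calls changed with abundance. The median gene of the authors' deposited table had a mean of 0.545 CPM and the lowest 0.383 CPM, and 74.4% of the genes lay under 1 CPM. The deposited CPM values sum to 1137634, more than the scale's own total, so that low values hold an added prior amount; above the lowest value the median gene stood at 0.162 CPM. All abundance classes use the values as deposited, which are means over the libraries of the fit. At like mean abundance the outer band, described further on, lay 0.722 higher on the log2 scale on the positive side. Positive calls had a median of 0.881 CPM and negative calls of 1.53 CPM. Positive and negative calls may thus fall into different classes at like levels. How far this shapes the shares by class was not tested. Under 0.5 CPM, 3394 of the 3724 called genes were positive, a share of 91.1% (90.2 to 92.0%). The positive share was 68.1% (67.4 to 68.8%) from 0.5 to 1 CPM and 59.1% (58.4 to 59.8%) from 1 to 10 CPM. Negative calls were the more numerous at higher abundance. The positive share was 47.0% (45.4 to 48.7%) from 10 to 100 CPM, 29.9% (25.8 to 34.3%) from 100 to 1000 CPM and 29.1% (17.6 to 42.9%) at 1000 CPM and over, the last class holding 91 genes and 55 calls.

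**Figure D1:**
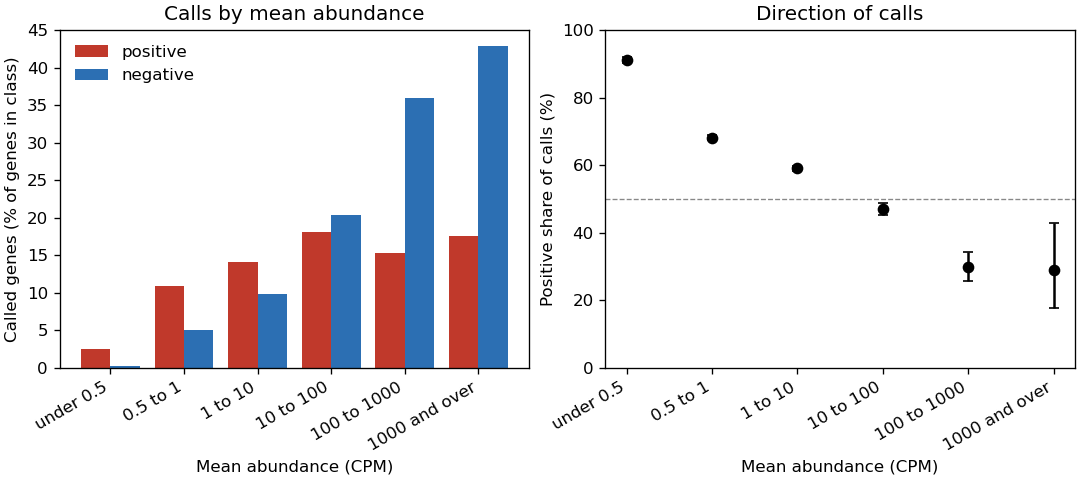
Left, called genes as a percentage of all genes in each class of mean abundance (CPM), positive in red and negative in blue. Right, the positive share of the calls (%) with exact 95% intervals and a dashed line at 50%. The share falls from 91.1% under 0.5 CPM to 29.1% at 1000 CPM and over. How far averaging over the libraries of the fit shapes this fall was not tested.

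Abundant genes were called most often. The called share of the authors' deposited table was 2.71% under 0.5 CPM, 16.1% from 0.5 to 1 CPM, 23.9% from 1 to 10 CPM, 38.4% from 10 to 100 CPM, 51.4% from 100 to 1000 CPM and 60.4% at 1000 CPM and over. Genes with a large difference were also called more often at higher abundance. Of genes listed with a difference of at least 4-fold, 9.81% were called under 0.5 CPM, 55.5% from 0.5 to 1 CPM, 78.2% from 1 to 10 CPM and 90.3% from 10 to 100 CPM. From 100 to 1000 CPM, 363 of 370 such genes were called, and at 1000 CPM and over all 53. Of genes listed at 4- to 5-fold, 0 of 10773 were called under 0.5 CPM and 257 of 4757 from 0.5 to 1 CPM. From 1 to 10 CPM 1602 of 2453 were called, and from 10 to 100 CPM 289 of 328. Listed differences of this size were thus seldom called under 1 CPM. A listed fold can arise without a true difference, so these shares do not measure how often a true difference would be found.

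**Figure D2:**
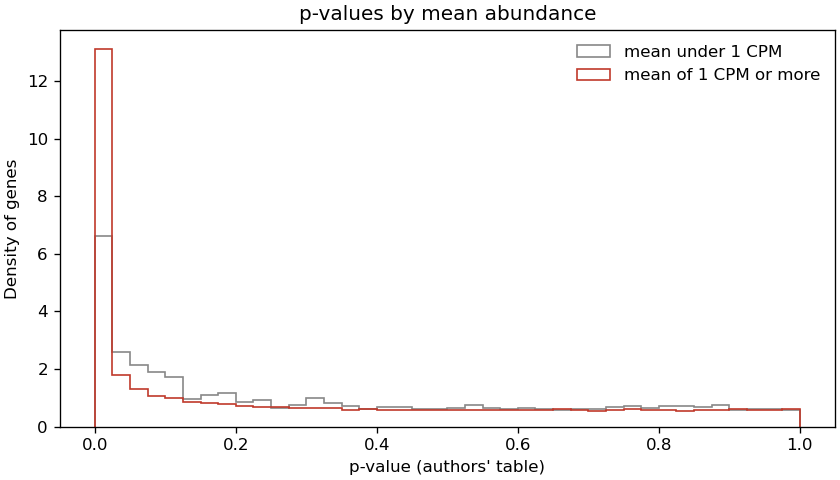
Density of genes (vertical axis) by p-value in the authors' table (horizontal axis), for genes with a mean under 1 CPM in grey and of 1 CPM or more in red. Both curves peak next to 0, and the red peak is the higher.

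A small number of genes made up much of the summed CPM. By mean CPM in the authors' deposited table, the top 10 genes held 14.7% of the total, the top 100 genes 29.9% and the top 1000 genes 50.7%. Among the top 100 genes, 17 were called positive, 40 negative and 43 were not called. Among the top 1000 genes the numbers were 155, 366 and 479. Positive calls together held 16.6% of the summed CPM, negative calls 24.7% and genes without a call 58.7%. With the top 100 genes left out, the shares of positive and negative calls were 14.5% and 20.4%. All these sums hold the prior amount, which weighs most on scarce genes. The shares of the top genes are thus somewhat too low and that of genes without a call too high.

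Many of the large folds lay on a sharp outer edge. Among genes of at least 1 CPM and 16-fold difference, 2876 of 6028 positive and 1365 of 4043 negative genes fell into a narrow outer band, delimited as a strip along which fold and abundance rise together. On the log2 scale the band was 0.20 wide on the positive and 0.26 wide on the negative side, and an empty interval of 0.44 and of 0.64 parted it from the other genes considered. The authors called 2443 of the positive and 1076 of the negative band genes, and left 433 and 289 uncalled. Called band genes made up 20.3% of the positive and 11.5% of the negative calls of at least 1 CPM. Most band genes were scarce, with medians of 1.73 and 1.74 CPM, but 230 positive and 117 negative ones had at least 10 CPM, and 17 and 22 at least 100 CPM. Of the 439 genes called with a fold of at least 1000, 307 lay in the band, as did TRINITY_DN435_c0_g1, TRINITY_DN372_c0_g2 and TRINITY_DN24708_c1_g1. TRINITY_DN613_c0_g1, with the largest positive fold, lay outside it.

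**Figure D3:**
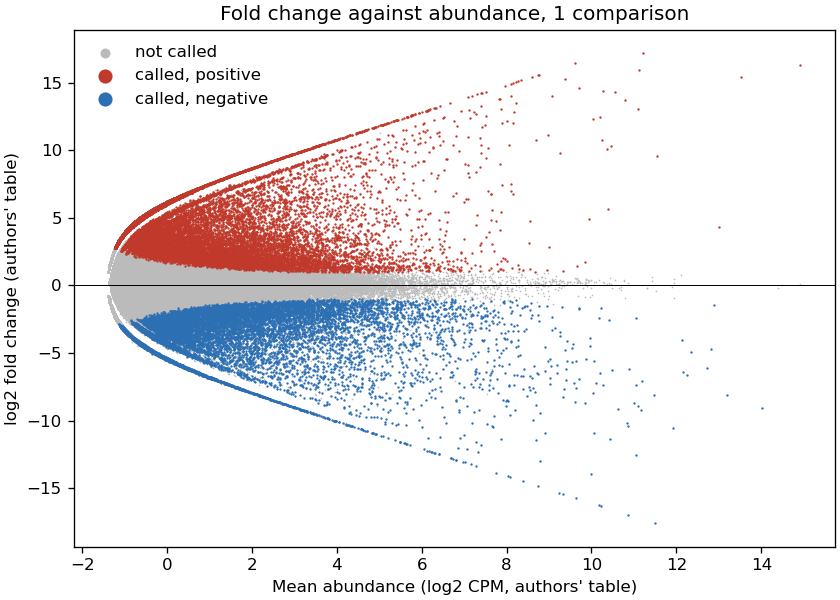
log2 fold change (vertical axis) against mean abundance in log2 CPM (horizontal axis) for 322502 genes of the authors' table, with called positive genes in red, called negative genes in blue and genes not called in grey. From 1 CPM upwards the outer red and blue lines are the bands of 2876 positive and 1365 negative genes, parted there by an empty interval from the other genes of at least 16-fold difference.

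No comparison that separates the inner arm core from both other tissues, and none between animals, is given here, because both need values per library or a stated contrast.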

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

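The threshold of an adjusted p under 0.01 had been planned; all other alternatives in this part were chosen after the table and its overall counts were seen. Fewer genes passed at an adjusted p under 0.01 (15720 positive, 8344 negative, 65.3% positive), under the Benjamini-Yekutieli adjustment (12660, 6656, 65.5%) and under the Bonferroni adjustment (5452, 2596, 67.7%). An adjusted p under 0.1 gave the highest counts (38575, 22001), and no fold minimum left them nearly as they were (26678, 14920). The share was 64.9% with a fold of at least 4. Filters on abundance, with p-values adjusted again over the genes left, moved the direction: positive calls made up 60.0% among genes of at least 0.5 CPM (25724 positive and 17147 negative calls, more in all than without the filter), 56.2% among genes of at least 1 CPM (13906 positive calls) and 44.5% among genes of at least 10 CPM (1983 positive, 2476 negative), which reverses the excess. The cause of these changes was not tested. With log2 fold changes moved by the median the share was 58.04%. Counting each assembly cluster once per direction gave 63.7%. The 41573 calls lay in 37957 clusters, so this count could lower the share only a little. Splitting of a locus within its cluster is thus not the whole cause of the excess. A locus whose pieces fell into different clusters is not covered by this count and stays open as a cause. Over the 11 alternatives positive calls ranged from 1983 to 38575 and negative calls from 2476 to 22001. No paired analysis was possible because the table holds no values per library, and for the same reason the planned changes of normalization, tool, low-count filter, replicate block, unit of replication and samples, leaving out each animal included, were not run. Calls were rare at low abundance: 9.81% of genes listed with a difference of at least 4-fold under 0.5 CPM were called.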

Other observations

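All tests in this part were chosen after the table and its overall counts were seen. Those of low abundance, scaling and pairs of a cluster had their bounds set before their own values were computed, while the test of unequal libraries and both tests of the outer band were chosen after the result was seen. Of 264275 assembly clusters, 43341 held several genes, and 3189 held at least 2 called genes. Called genes of a cluster mostly shared their direction: 1890 of these clusters were positive throughout, 855 negative throughout, and 444 (13.9%) held calls of both directions. Random reassignment of directions within abundance classes gave 1466 to 1655 clusters of both directions. Genes in clusters of 2 were called more often (14.9%) than genes alone in their cluster (11.9%), at a median of 0.642 against 0.509 CPM; this difference was not tested.

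More genes were called with a positive than with a negative fold change. From 10 CPM upwards the positive share was 44.5%, so the excess lay in genes under 10 CPM. Genes under 1 CPM account for part of the excess but not all of it: the positive share fell from 64.1% to 56.2% from 1 CPM upwards (55.6 to 56.9%), just above the bound of 55%. Provided that the implied errors hold, which was not tested for genes with few reads, an off-centre library scaling is likewise not the whole cause. It stays open for a part. Moving every gene by 0.14, the median over genes of at least 1 CPM, lowered the share from 64.1% to 58.04% (57.6 to 58.5%). The median over genes of at least 10 CPM was -0.004 and would move next to nothing. Unequal numbers or depths of libraries on the 2 sides may contribute. In the 5 abundance bins of at least 100 genes the outer 0.1% of positive folds reached further than that of negative folds, by a median of 0.91 on the log2 scale (0.55 to 1.01). In the bins of 1146 and 323 genes this outer 0.1% rests on the outermost genes alone. In the sixth bin, of 70 genes, the negative side reached further (-17.55 against 17.08). A larger number of positive genes at the edge can itself widen this offset, and the outer band lay only 0.722 higher on the positive side. How far the outermost folds reach does not show that more genes would be called positive. A difference between the tissues in how many rare transcripts they hold stays open and was not tested.

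Clusters that hold calls of both directions would be worth following, since alternative copies or forms of a gene in different tissues is a biological explanation that was not tested. Among 4118 pairs of called genes of a cluster, 12.5% were opposite, against 43.3 to 48.3% in random pairs. This excludes that all clusters join unrelated genes, but the bound first set was wrong for the opposite pairs themselves, because a mixture with 27.5% unrelated pairs would give the same share, and unrelated genes placed in a cluster therefore stay a possible explanation for them. Opposite pairs were not confined to scarce genes, since 8 of 122 pairs with both genes at 10 CPM or more were opposite, 6.56% (2.87 to 12.5%). The share exceeded the bound set for chance calls. That bound was too low, because false calls at an adjusted p under 0.05 could give a share within this interval. Chance calls therefore stay a possible source. Only 2 clusters held calls of both directions at 4-fold and 10 CPM or more.

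The outer band of fold against abundance is a candidate set of genes with no reads on 1 side of the comparison. A step between 0 and 1 read would leave the empty interval at lower abundance too, in genes that did not define it. Of genes of 0.5 to 1 CPM in or next to that interval, 0.669% fell inside it on the positive side (61 genes, with 7501 at or above the band) and 0.269% on the negative side (27 and 5897), but estimated counts need not be whole, and the hypothesis was found on the same table. The largest log2 fold change of all genes differed between the 6 abundance bins by 8.48 on the positive and 9.64 on the negative side. The band had been delimited as a strip along which fold and abundance rise together, so this outcome was given beforehand. The values speak only against a software limit on the fold that is the same at every abundance. A limit that rises with abundance is not covered. On this hypothesis 4241 genes of at least 1 CPM were seen on a single side, 67.8% of them on the positive side, and the 433 and 289 of them left uncalled would be genes read in few libraries of that side. The 7501 positive and 5897 negative genes of 0.5 to 1 CPM at or above the band would join them. The listed folds of all these genes would then depend on the prior amount added in the fit. Counts per library, not analysed here, would decide both.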
